A study of Mus musculus with 6 samples.

How the data were processed

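Gene expression was measured on 6 Affymetrix mouse arrays, 3 titled PBS, here called control, and 3 labelled MBELN. MBELN is a preparation of exosome-like nanoparticles from mulberry bark. Per the labels, each treated mouse took particles in 100 µl by mouth every day until day 7, and colon was then collected from C57BL/6J mice. Biotin-labelled cRNA was made from 90 ng of total RNA, per the labels' protocols. The same label also names an amplicon sequencing panel, which the values do not resemble, since the identifiers are array probe sets.

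The deposited table holds 28846 probe sets as log2 expression between 3.38 and 19.93. The scale was read from the values, whose upper end is log2 of 1000000. The Transcriptome Analysis Console, version 4.0, is named in the submitters' processing notes. The summarisation and the normalisation between arrays are not given in the sources used here. Medians of the arrays lay close together and their spreads did not, so the values were used as deposited. Genes were not centred.

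Probe sets whose identifiers mark them as controls (6640, among them 5222 negative and 1324 positive controls) were left out of the tests, which left 22206. The platform annotation gave 1 symbol for 19572 of these, several symbols for 0 and none for 2634. All 19572 matched a gene of the reference table by Entrez number, and 0 symbols needed updating. These are 19505 different symbols, of which 55 have several probe sets. For those the probe set with the highest mean over the 6 arrays stood for the gene in lists and in the text. No genome build was used, and positions are not reported.

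A probe set counted as above background on an array when it exceeded the 95th percentile of that array's negative controls. This threshold was chosen after the data were seen. Where every array of 1 group lay below it, the text gives for named genes the brighter group's mean over the mean of, per array, the higher of the threshold and the probe set's own value, as "at least N-fold". The brighter group's mean includes any of its arrays below the threshold, so this bound is not strict. Where the bound is under 1, or both groups lay below the threshold, the measured means are given. The targets keep their fitted log2 differences, which measure no fold for a gene not above background. For arrays, their number limits the precision.

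Groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all 22206 probe sets and a threshold of 0.05. A second count, fixed in advance as a description, took an unadjusted p under 0.05 with a change of at least 1.5-fold. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation and with fry. Before the data were examined, 48 lists were fixed, and 47 had the 5 measured members a test required. The 5 lists called held-out lists were written later, once the genes leading each array had been seen. Genes were ranked as leading on an array by their excess over the highest other array, with control 2 left out of the others. Genes among the leading 70 of any array were left out of the held-out lists. Each list's median on an array, taken against the other arrays without control 2, was ranked among 10000 random lists of the same size, matched on mean expression in 40 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for summaries and plots.

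The genes named were set by a rule written in advance. It takes 12 genes in each direction among those past the threshold, and fills empty places, as values that did not pass, with the smallest unadjusted p among changes of at least 1.5-fold. Predicted genes, receptors of smell and taste, small RNAs and antigen receptor segments take no place. It adds up to 4 members of each called list by smallest unadjusted p, up to 2 members of other lists described, and 9 targets, of which 8 were measured. Hspa8 is not analysed here. Marker genes named for single arrays fall outside the rule and were chosen after their values were seen.

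The fit was tested on simulated data with 200 changed probe sets among 22206. At the spread of these arrays it recovered 0% of 50 changes of 1 log2 unit, 0% of those of 2, 6% of those of 4 and 70% of those of 8, with 3 false calls. At a standard deviation of 0.3 it recovered 78% of changes of 1 log2 unit and 100% of the larger sizes, with 10 false calls.

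Alternatives were a filter on dim probe sets at the 25th percentile or the median, quantile normalisation, equal medians, an intensity trend with a robust prior, array weights, the replicate number as a block and leaving out each array in turn. For genes a plain t statistic was also run, and for lists the mean of a gene's probe sets. A fit without control 2 and control 3 was added after the data were seen. All 6 sample columns were used.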

Results

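Samples labelled colon were compared between mice given mulberry bark nanoparticles (MBELN) by mouth for 7 days and control mice. There were 3 arrays per group, and the aim was to see which genes differ after treatment. Arrays are called by their labels throughout (control 1 to 3, MBELN 1 to 3), because several did not show the genes of the labelled tissue. The labels do not say that each array came from a separate animal, so p-values measure only the spread between these samples, which may be technical. Within each group that spread, and each SD, also holds the different tissue genes described below and, in control, the flat control 2. The share of probe sets above background was 26.0% on control 1, 0.311% on control 2, 20.7% on control 3, 27.7% on MBELN 1, 14.2% on MBELN 2 and 23.1% on MBELN 3. The median log2 value lay between 5.66 on MBELN 3 and 6.06 on control 2. The standard deviation over probe sets was 1.19 on control 2 and between 2.55 and 2.85 on the other arrays.

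The array labelled control 1 carried the genes of colon epithelium and smooth muscle. Its median was 17.30 for 24 colonocyte markers and 15.99 for 22 smooth muscle markers, on the log2 scale. On the other 5 arrays the colonocyte median lay between 4.81 (control 3) and 6.17 (MBELN 1). Muc2, the main secreted mucin of goblet cells, was at 19.59 on control 1 and at 4.49 to 6.28 elsewhere. Zg16, a goblet cell lectin, was at 19.59 against 4.92 to 5.47, and Car1, a carbonic anhydrase of colonocytes, at 19.29 against 4.39 to 6.80. Posterior Hox genes, which mark the distal gut, had a median of 7.02 on control 1 and between 4.24 and 5.76 on the others, with Hoxb13 at 10.53 on control 1.

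The other arrays were led by genes of other tissues. Control 3 carried neuronal genes: the 19 enteric neuron and glia markers had a median of 9.46, against 4.77 to 5.99 on the other arrays. Snap25 and Syt1, which act in synaptic vesicle release, were at 19.61 and 19.91, and Mbp, a myelin protein, at 18.46. On MBELN 1 the cardiac myosin gene Myh6 was at 19.32 and the natriuretic peptide gene Nppa at 19.93, and endothelial markers had a median of 10.09, against 5.44 to 6.92 elsewhere. MBELN 2 had a median of 14.29 for 20 squamous epithelium markers and 13.42 for 18 skeletal muscle markers, while no other array exceeded 5.54 for either list. The keratins Krt5 and Krt14 were at 19.69 and 19.68 there, and the fast muscle myosin Myh4 at 18.78. MBELN 3 had a median of 19.78 for 15 liver markers, against 4.95 to 7.51 on the others. Albumin (Alb) was at 19.93, the fibrinogen chain Fgb at 19.42 and the urea cycle enzyme Cps1 at 18.92.

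Lists of other genes of these tissues, written after the leading genes had been seen and leaving those out, were highest on the same arrays. The held-out brain list had its highest median on control 3 (11.49, next array 6.04), the heart list on MBELN 1 (11.21, next 5.74) and the skin list on MBELN 2 (10.80, next 5.58). The liver list was highest on MBELN 3 (15.15, next 6.02) and the colon epithelium list on control 1 (10.41, next 5.66). Of 31 held-out colon epithelium markers, 19 (61.3%, 95% Wilson interval 43.8% to 76.3%) were above background on control 1. The highest number on another array was 4 (12.9%, 5.13% to 28.9%), on MBELN 3. Wilson intervals treat the genes of a list as independent, which they are not, and measure no spread between samples.

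**Figure D1:**
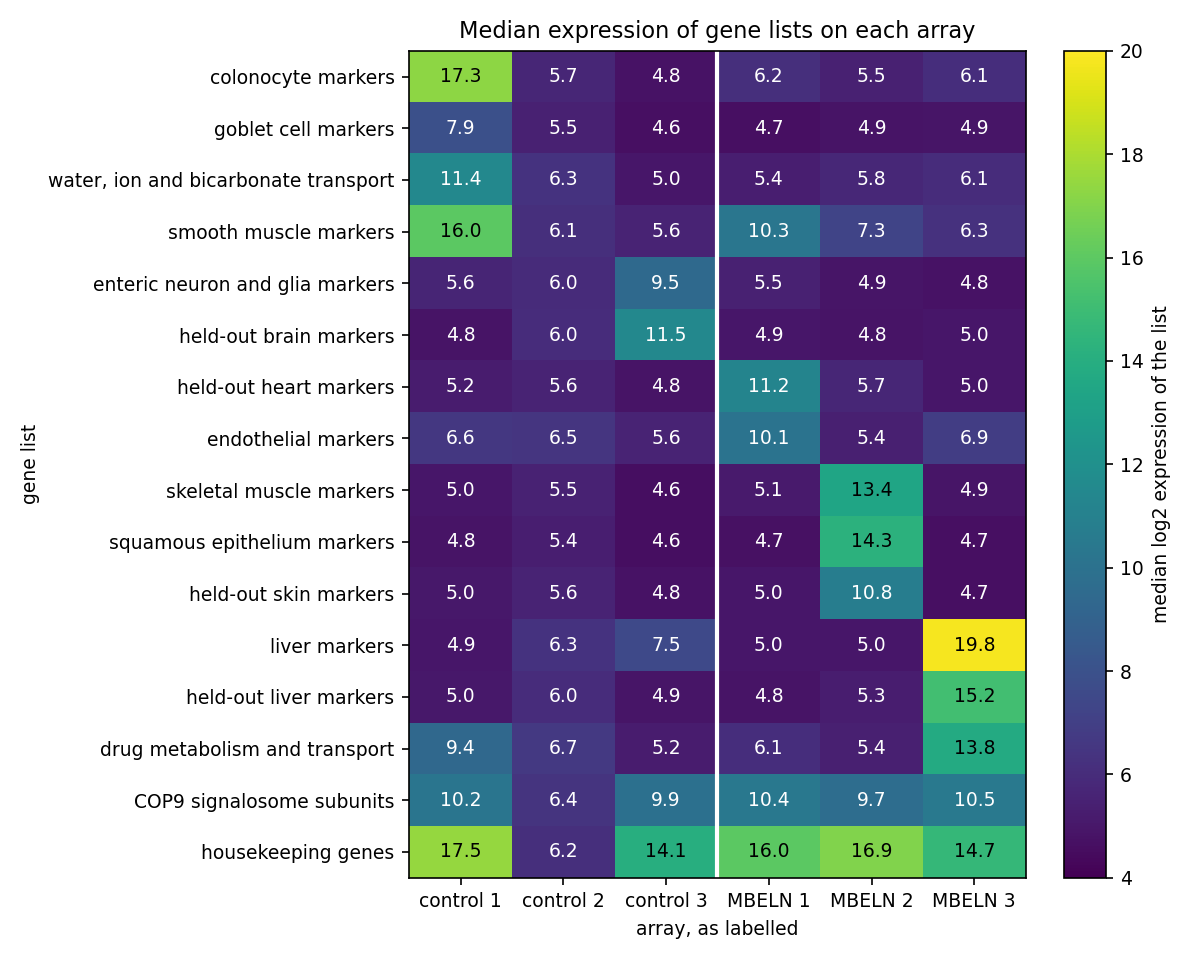
Median log2 expression of gene lists (rows) on each array (columns, as labelled; the white line parts the groups). Held-out lists were chosen after the data were seen. Colonocyte markers stand at 17.30 on control 1 and liver markers at 19.78 on MBELN 3, and control 2 lies between 5.37 and 6.69 for every list drawn.

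Control 2 carried none of these gene groups. Its housekeeping median was 6.17, against 14.05 to 17.48 on the other arrays, and its 28 ribosomal protein genes had a median of 6.82, against 13.77 to 17.44. Positive controls lay 0.326 log2 units below negative ones on control 2 (difference of medians -0.326) and 2.54 to 3.94 above them elsewhere. The hybridisation spikes bioB, bioC, bioD and cre were at 4.05, 6.19, 8.26 and 10.32 on control 2, each lower than on the other arrays (bioC 8.70 to 9.66, bioD 9.41 to 10.73), and the first 3 lay under that array's background threshold of 10.11.

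Arrays of one group were no more alike than arrays of different groups. Across probe sets, which are not independent replicates, the mean Pearson correlation was 0.523 within groups and 0.530 between them (exact permutation test over 10 splits, one-sided, p = 0.8, where the smallest p possible is 0.1). Without control 2 the means were 0.686 and 0.689.

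In limma's test between arrays labelled MBELN and control, 0 of 22206 probe sets passed, and the smallest adjusted p was 0.936. Since only control 1 carried colon genes, this test cannot show whether colon responded to MBELN. At an unadjusted p under 0.05, 422 probe sets stood out, where chance alone would give 1110.3, and a plain t statistic gave 361. All 422 also differed by at least 1.5-fold, 304 higher and 118 lower on MBELN arrays. Of these, 102 were above background on no array, 139 only on MBELN arrays, 46 only on control arrays and 135 in both groups. The groups did not overlap for 1517 probe sets (6.83%), where chance gives 10%.

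Among the 12 genes that the naming rule took as higher on MBELN arrays, Me1, Gpam and Acacb belong to the lipid synthesis list. Me1, the malic enzyme that supplies NADPH, was 13.44 ± 1.75 (SD, n = 3) in MBELN and 7.32 ± 1.66 (n = 3) in control, a log2 fold change of 6.13 (SE 1.22). Gpam, the first enzyme of glycerolipid synthesis, was 12.58 ± 1.01 against 7.71 ± 1.48. Acacb, an acetyl-CoA carboxylase, was 7.20 ± 0.30 against 4.74 ± 0.25, above background on no array. Hmox1, which degrades haem, was 10.99 ± 0.42 against 7.11 ± 1.19, with a log2 fold change of 3.88 (SE 0.72). Me1, Gpam and Hmox1 were each above background on only 1 control array, so their differences are fitted values and not measured folds. For genes below background on every control array only a bound could be given. Palmd was at least 9.85-fold higher on MBELN arrays, Dhrs3, a retinal reductase, at least 3.09-fold, and H2-Q5, an MHC class I gene, at least 2.56-fold. Cd44, a hyaluronan receptor, was at least 1.56-fold higher, the interleukin 1 receptor gene Il1r1 at least 1.30-fold and the Wnt co-receptor gene Lrp5 at least 1.02-fold. Pacsin3, not above background on control arrays, had means of 8.59 in MBELN and 6.05 in control, and Fam180a, above background on no array, 7.53 and 5.20. Each had an adjusted p of 0.936.

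Of the genes lower on MBELN arrays, Tac1 and Chgb belong to the enteroendocrine list. Tac1, the precursor of substance P, was 10.15 ± 1.49 (SD, n = 3) in control and 5.45 ± 0.45 (n = 3) in MBELN, and Chgb, a secretory granule protein, 9.12 ± 1.90 against 4.37 ± 0.21. Both were highest on control 3, at 11.60 and 11.18. The bounds were at least 2.97-fold lower for Tac1, 1.45-fold for Chgb, 2.90-fold for the phosphatase gene Ptprr and 2.29-fold for Bcas1. Mgat4c, Atp8a2 and Irak1bp1 were above background on 1 control array and 0 MBELN arrays, and their bound was under 1, so no fold is given. Their means were 8.53, 7.72 and 8.44 in control and 4.99, 4.65 and 5.96 in MBELN. Tox3, Kcnn3, a potassium channel, Slc6a20a, a proline transporter, Hif3a and Elapor1 were above background on no array. Their means were 7.53, 6.53, 7.46, 6.70 and 7.42 in control and 5.25, 4.52, 5.27, 4.64 and 4.70 in MBELN. All 24 named genes had non-overlapping groups, and none passed the adjusted test. Choosing genes by the smallest p favours such separation, so it is no added support. On the flat control 2, every lower gene but Ptprr (10.59) lay under that array's threshold of 10.11. Their separation therefore rests in part on values there that are not measured expression.

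**Figure D2:**
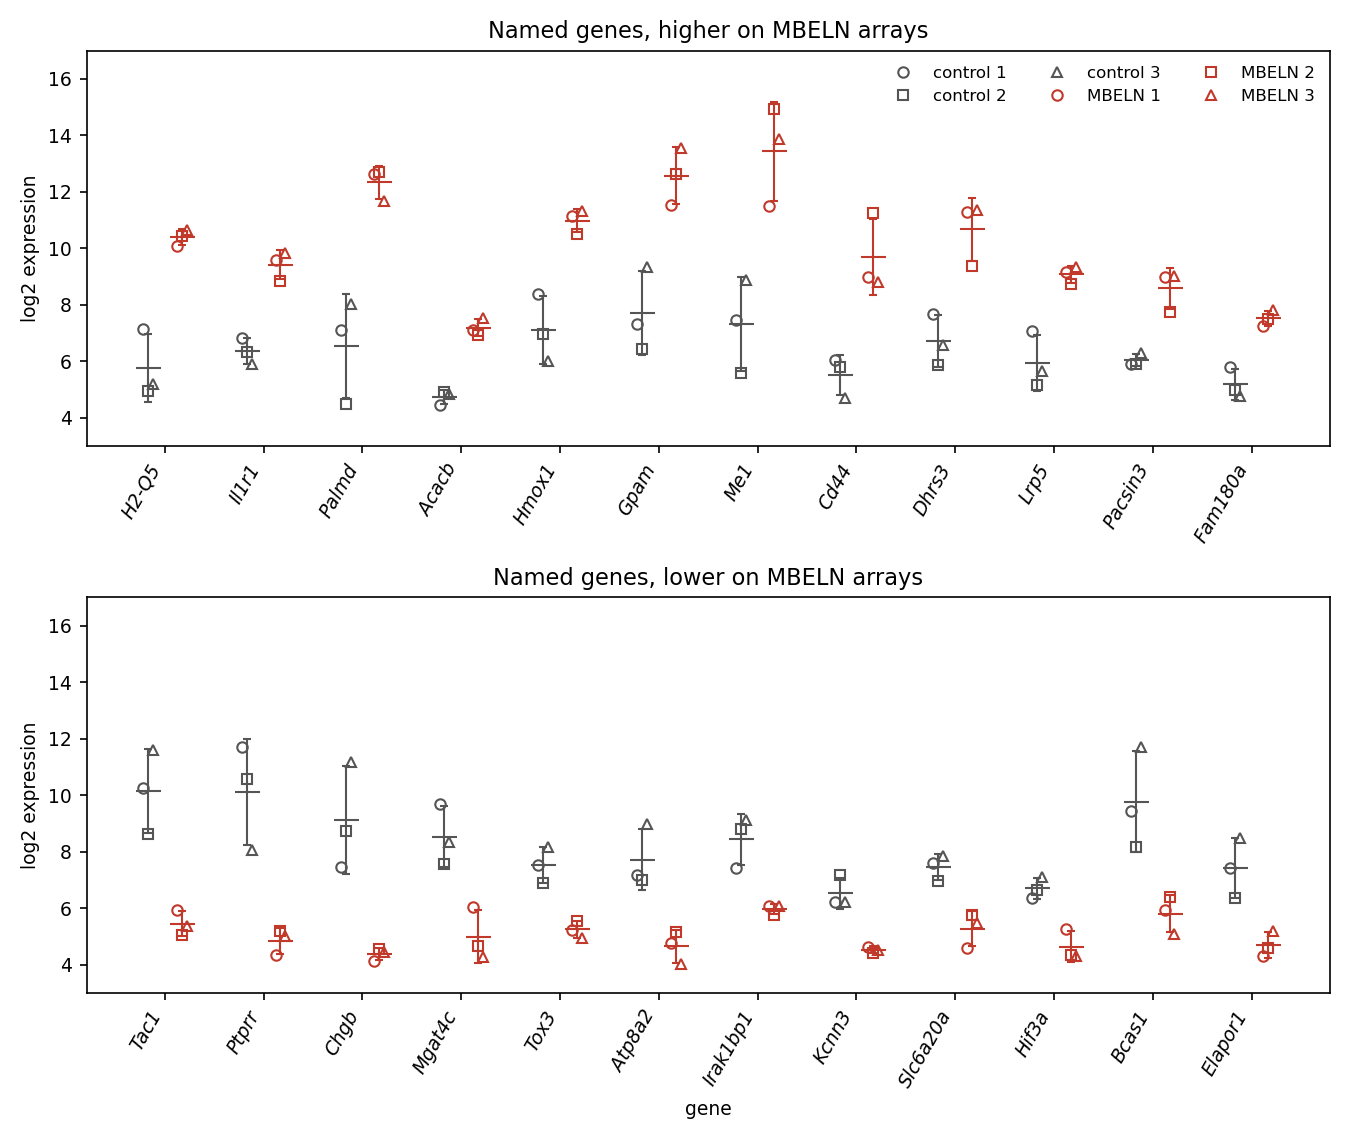
Log2 expression (vertical axis) of the 24 genes taken by the naming rule, 12 in each direction, upper panel higher and lower panel lower on MBELN arrays. Points are single arrays, bars the mean and SD of 3 arrays. Palmd lies at 11.68 to 12.71 on MBELN arrays and at 4.49 to 8.04 on control arrays, and its adjusted p is 0.936.

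By camera at the preset correlation of 0.01, 25 of 47 gene lists passed, 19 higher and 6 lower on MBELN arrays. The estimated correlation was 0.33 for fatty acid oxidation, 0.86 for oxidative phosphorylation and 0.94 for ribosomal proteins, so the preset p-values of these lists are too small. It was -0.012 for enteroendocrine markers. The splits of the 6 arrays gave 21 to 29 called lists, so a count of 25 does not set the labelled groups apart. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), and fry called 0 (1 unadjusted). Of the 25 lists, 20 lost their call or turned when some single array was left out, and 5 did not: fatty acid oxidation, lipid synthesis, oxidative phosphorylation, enteroendocrine markers, and enteric neuron and glia markers.

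Fatty acid oxidation genes were higher on MBELN arrays as a list, 26 of 26, with a median log2 fold change of 3.47 (camera adjusted p = 6.2e-13, and adjusted p = 0.736 with an estimated correlation). Of its members, 0 passed over all genes and 0 adjusted over the list alone. Hadha, of the mitochondrial trifunctional protein, was 16.36 ± 1.99 in MBELN (SD, n = 3), with a log2 fold change of 6.04 (SE 1.78). Cd36, a fatty acid transporter, had one of 6.71 (SE 2.10) and was above background on only 1 control array. Angptl4, which inhibits lipoprotein lipase, was not above background on control arrays and was at least 1.43-fold higher on MBELN arrays. The list's medians were 11.85 on MBELN 1 and 13.31 on MBELN 3, the arrays with heart and liver markers, 8.91 on control 1, 8.80 on MBELN 2, 6.57 on control 3 and 6.54 on control 2, the flat array, where 0 of 26 members were above background. Without control 2 the median change was 3.08. Lipid synthesis genes were higher as a list, by a median of 3.03, with 18 of 18 differences above 0 (adjusted p = 1.2e-08, and adjusted p = 0.736 with an estimated correlation), and 3 members passed when adjusted over the list alone, against 0 over all genes. The list's median was 14.07 on MBELN 3, the array with liver markers, 9.75 on MBELN 2, 9.27 on control 3, 8.53 on MBELN 1, 7.91 on control 1 and 5.46 on control 2, and the median change was 1.74 without control 2 and 1.21 without MBELN 3. Oxidative phosphorylation was higher as a list, by a median of 2.92 (adjusted p = 5.2e-09, and adjusted p = 0.736 with an estimated correlation), with medians of 17.05 on MBELN 1, the array with heart markers, and 6.41 on control 2. Between these lay control 1 (13.64), MBELN 3 (13.13), control 3 (11.88) and MBELN 2 (10.41). None of its 37 members was under an unadjusted p of 0.05, and the median was 0.83 without control 2 and 1.33 without MBELN 1. The call was lost without both control 2 and control 3 (median 0.32). Housekeeping genes were higher as well, by a median of 2.66 in 13 of 14 members (adjusted p = 0.00214, and adjusted p = 0.736 with an estimated correlation), and stood at -0.23 without control 2. Enteroendocrine markers were lower by 1.81 as a list, with 1 of 20 higher on MBELN arrays (camera adjusted p = 9.6e-09, and adjusted p = 0.118 with an estimated correlation), and 2 members passed when adjusted over the list alone. Its medians were 6.45 on control 3, the array with brain markers, 6.31 on control 1, the array with colon markers, 5.91 on the flat control 2 and 4.73 to 5.04 on MBELN arrays, each under its array's background threshold. Of the 20 members, 7 were above background on control 3, 4 on control 1, 0 on control 2 and at most 1 on an MBELN array. The change was -1.12 without control 1. Enteric neuron and glia markers were lower by 2.10, with 2 of 19 higher (camera adjusted p = 1.0e-06, and adjusted p = 0.736 with an estimated correlation), and 0 passed adjusted over the list alone. The median was 9.46 on control 3, the array with brain markers, 5.63 on control 1, 5.99 on control 2 and 4.77 to 5.45 on MBELN arrays, and the change was -0.72 without control 3.

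Several calls rested on a single array. Liver markers were higher by a median of 4.09 in 15 of 15 members (adjusted p = 0.000733, and adjusted p = 0.736 with an estimated correlation). The median was -0.68 without MBELN 3. Squamous markers were higher by 2.97 (camera adjusted p = 0.00214, and adjusted p = 0.736 with an estimated correlation) and stood at -0.19 without MBELN 2. Their call was also lost without control 3 (camera adjusted p = 0.0696). Skeletal muscle markers were higher by 3.77 (adjusted p = 6.2e-06, and adjusted p = 0.736 with an estimated correlation) and at 0.15 without MBELN 2. Colonocyte markers were lower by a median of 2.65 (log2 fold change -2.65, adjusted p = 0.0025, and adjusted p = 0.754 with an estimated correlation) and at 0.67 without control 1. Goblet cell markers had a median of -1.39 (adjusted p = 5.4e-06, and adjusted p = 0.736 with an estimated correlation) and -0.19 without control 1, where the call was lost. Ribosomal protein genes had a median of 3.36 (adjusted p = 2.3e-08, and adjusted p = 0.736 with an estimated correlation) and 0.74 without control 2, where the call was lost. No member of these 6 lists passed, either over all genes or adjusted over the list alone.

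Lists linked to the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, and to the COP9 signalosome, a regulator of protein degradation, were fixed in advance. The 15 AhR target genes were not called (median log2 fold change 0.74, 11 of 15 higher, adjusted p = 0.0874). All 10 COP9 subunits were higher on MBELN arrays, by a median of 1.14 (camera adjusted p = 0.0132, and adjusted p = 0.736 with an estimated correlation). The median was -0.14 without control 2, where the call was lost. It was also lost without MBELN 1, with array weights and with the filter at the median. Cops4 and Cops5 had log2 fold changes of 1.62 and 1.99, and both were lowest on control 2, at 6.91 and 5.34. NRF2 targets, which defend against oxidants, were higher by a median of 1.86 (17 of 19 higher, camera adjusted p = 6.5e-05, and adjusted p = 0.736 with an estimated correlation), and lost the call without MBELN 3 (median 1.19). Without both control 2 and control 3 the median was 0.27. Without control 2 alone the median was 0.80, and without control 1 it was 2.87. The list stood at 12.81 on MBELN 3, the array with liver markers, at 9.32 and 8.49 on MBELN 1 and 2, and at 9.68, 5.78 and 8.06 on control 1, 2 and 3. For NRF2 targets 1 member, Hmox1, passed when adjusted over the list alone.

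None of the 8 measured targets passed, and 1 of them, Ahr, had an unadjusted p under 0.05. Ahr itself was 7.91 ± 0.95 (SD, n = 3) in MBELN and 5.74 ± 0.93 (n = 3) in control, a fitted log2 difference of 2.17 (SE 0.75) with an adjusted p of 0.936, and was above background on 1 of 3 MBELN arrays and on 0 control arrays. Its target genes Cyp1a1, Ahrr and Tiparp were above background on no array, with fitted log2 differences of -0.29 (SE 0.72), 0.40 (SE 0.48) and 0.68 (SE 0.95), so these values do not show whether they responded. Cyp1b1 was above background on 1 MBELN array and 0 control arrays, with 1.16 (SE 0.97). Cops8, a COP9 subunit, was 8.80 ± 0.89 against 7.81 ± 2.26, a log2 fold change of 0.98 (SE 1.22). The antimicrobial lectins Reg3b and Reg3g had fitted log2 differences of 0.24 (SE 0.57) and 0.17 (SE 0.45) and were above background on no array. Without control 2 the signs of Cyp1a1 (0.36), Tiparp (-0.33) and Cops8 (-0.27) turned.

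**Figure D3:**
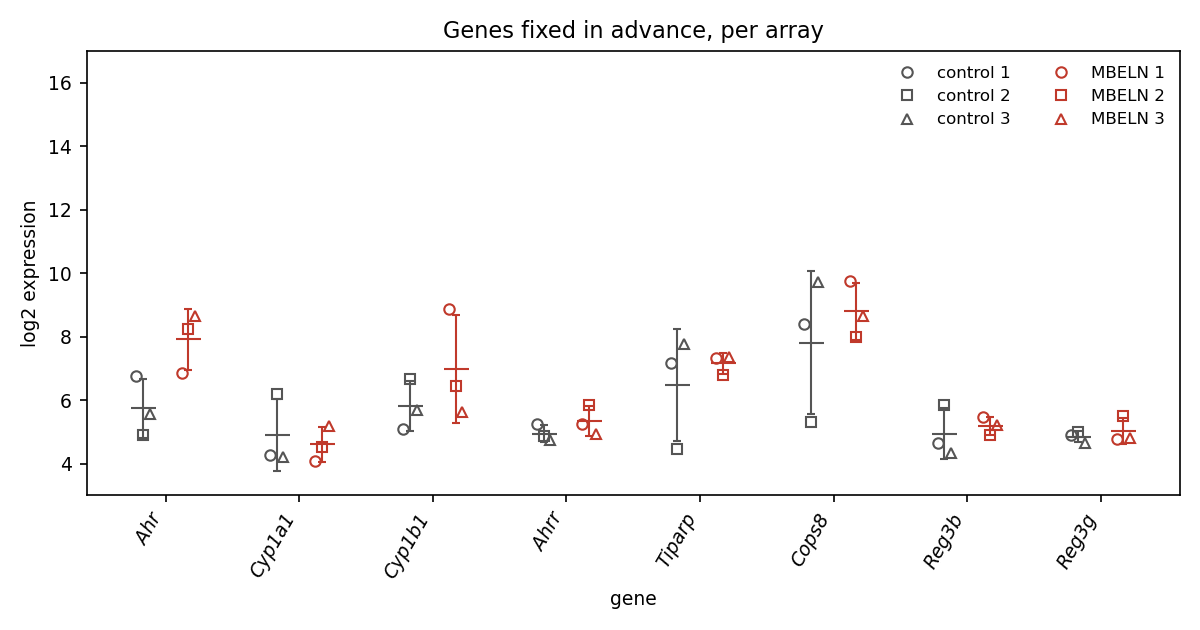
Log2 expression (vertical axis) of the 8 measured targets on each array. Points are single arrays, bars the mean and SD of 3 arrays. Cops8 on control 2 (5.32) lies below its other values, which run from 7.99 to 9.76.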

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

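The fit without control 2 and control 3 was chosen after the data were seen, and the other alternatives before. The count of genes past the adjusted threshold was 0 in every alternative chosen before, and the 8 targets gave 0 in every alternative. In the added fit, which sets control 1 alone against the MBELN arrays and assumes that the lone array varies like the others, 14 probe sets passed, all lower on MBELN arrays. Leaving out every array without colon markers leaves 1 array and no test. The count at an unadjusted p under 0.05 and 1.5-fold was 197 with a filter at the median (fewer probe sets tested), 723 with array weights and 1111 in the added fit. It ranged from 296 to 1380 when single arrays were left out, the highest without control 1. The cause was not tested for the last 3. Called lists numbered 15 in the added fit, 0 with an estimated correlation and 0 by fry, and 18 to 27 without single arrays. Setting the medians equal moved the median log2 fold change of all probe sets to 0.11. Correlations of deviations were 0.11, 0.12 and -0.05 for arrays of the same replicate number, and -0.18 to 0.096 for arrays of different numbers. The values 0.11 and 0.12 were the highest, but all were low, so pairing by replicate number is not shown. The replicate block gave 624 in place of 422 probe sets, and control 3 correlated best with MBELN 1.

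Signs turned for some results. Cops8, COP9 subunits and housekeeping genes turned when the flat control 2, where they were lowest, was left out. Colonocyte, squamous and liver markers turned without the array that carried them (control 1, MBELN 2 and MBELN 3). For the other turns the cause was not tested. Cyp1a1 was 0.22 with array weights and 0.33 in the added fit, and Tiparp -0.027 in the added fit. Without single arrays the log2 fold change ran from -0.63 to 0.36 for Cyp1a1, from -0.33 to 1.33 for Tiparp, from -0.27 to 1.94 for Cops8, from -0.064 to 0.70 for Reg3b and from -0.056 to 0.29 for Reg3g. List medians ran from -0.14 to 2.09 (COP9), -0.70 to 2.75 (drug metabolism), -0.27 to 1.95 (cholesterol biosynthesis), -4.99 to 0.67 (colonocyte), -0.19 to 4.48 (squamous), -0.68 to 6.58 (liver) and -0.23 to 4.52 (housekeeping). In the added fit the medians were -0.28 (interferon response), -0.51 (drug metabolism), -0.83 (cholesterol biosynthesis), -0.29 (unfolded protein response), -0.97 (ribosomal proteins) and -0.31 (housekeeping). Of single genes, 429 alternative values stayed on the same side and 8 turned. Of lists, 286 stayed, 75 lost the call and 13 turned. Signal over background limits control 2 most, with 0.311% of probe sets above it.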

Other observations

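The tests on marker shares among the MBELN arrays, on brain markers of control 3, on control probe sets and on the spread of control 2 were chosen only after those results were seen, as was the comparison of intervals for the colon epithelium markers. The genes in the next paragraph were also chosen after their values were seen.

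The arrays held finer features of each tissue. MBELN 1 carried atrial genes: the atrial myosin light chain Myl7 was at 19.15, sarcolipin (Sln) at 19.58 and Bmp10 at 14.34, beside the ventricular light chain Myl2 at 19.93. Control 3 carried genes of excitatory neurons (Slc17a7, 16.20) and of inhibitory neurons (Gad1 13.52, Slc32a1 11.74, Sst 16.70). Albumin (Alb) was at 13.26 and Serpina1a at 9.43 on the same array. MBELN 2 carried hair follicle keratins (Krt71 15.30, Krt25 11.62) and the perinatal myosin Myh8 at 18.45. MBELN 3 carried major urinary protein genes (Mup20 19.89, Mup3 19.74) and Cyp2a5 at 19.91. Lcn2, an iron-binding acute phase protein, was at 16.56 on MBELN 2 and 16.88 on MBELN 3. The 219 probe sets of the Y chromosome had a median of 6.91 on MBELN 2 and 4.67 to 4.95 on the other arrays apart from control 2 (6.06). Each median lay under its array's background threshold (9.34 on MBELN 2), so no difference in Y chromosome expression is shown.

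The arrays labelled control 3 and MBELN 1 to 3 had few colon epithelium genes above background (at most 12.9% of the held-out markers and 29.2% of colonocyte markers, both on MBELN 3) and carried genes of brain, heart, skin with muscle, and liver. Colon RNA that carried RNA of another tissue would keep colon markers above background, and the interval of the 12.9% (up to 28.9%) lay below that of control 1 (from 43.8%), although the 75% predicted beforehand for control 1 was not reached (61.3%), so that this reading rests on the later comparison of intervals. A response of the colon to MBELN does not account for control 3, which is labelled PBS. There 85.7% of held-out brain markers were above background (Wilson interval from 68.5%), against 10.7% (up to 27.2%) on control 1. Whether the MBELN arrays shared a response cannot be read from their leading genes. These were ranked by their excess over all other arrays apart from control 2, so they could not be shared. Lists fixed in advance can be compared. Liver markers had a median of 19.78 on MBELN 3, against 4.95 on MBELN 1 and 4.99 on MBELN 2. Squamous markers stood at 14.29 on MBELN 2, against 4.74 on MBELN 1 and 4.68 on MBELN 3. For these genes the values argue against a response shared by the MBELN arrays. In 3 of 3 held-out lists (heart, skin, liver) the share above background on 1 array (79.3%, 64.7% and 100%) had a Wilson interval above those of both other MBELN arrays (shares of at most 20.7%). These lists were written because those tissues led those arrays, so their shares describe that pattern and are no separate test of it. All intervals here treat genes of one tissue as independent, so they are too narrow and measure no spread between samples. A response that differs between arrays was not tested. A mix-up of samples or labels stays open. Held-out lists were highest on the array predicted, by at least 2 log2 units, in 5 of 5 cases. All 5 lists were written for the tissues whose genes led those arrays, so this result is no separate test of a mix-up. Colon RNA that carried RNA of another tissue could give it too. The colonocyte median was 4.81 on control 3 and 5.49 to 6.17 on MBELN 1 to 3, against 17.30 on control 1. These values argue against colon as the main source of the RNA on these 4 arrays. Where a mix-up happened is not known.

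Control 2 was flat. Values written against the wrong probe set identifiers would keep the spread of a normal array, and its standard deviation was 46.6% of the lowest of the others. Failed labelling or hybridisation of the sample stays open: positive minus negative controls gave -0.326 there and at least 2.54 elsewhere, so sample signal may not have reached this array. The poly-A spikes phe, thr and dap, which go through labelling, all stood at 3.43 (dap 6.58 to 8.57 elsewhere), and the hybridisation spikes were lower than elsewhere too, with bioB at 4.05, bioC at 6.19 and bioD at 8.26 under the background threshold of 10.11 and cre at 10.32 (10.73 to 11.86 elsewhere), so the failed step stays open. No biological explanation was tested.

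With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. All 10 splits gave 0 genes past the adjusted threshold (real 0, highest other 0). For the unadjusted count, 9 of the 10 splits gave as many as the real 422. The highest other was 1382, with control 1, MBELN 1 and MBELN 3 together, where evenly spread p-values would give 1110.3. For called lists, 5 of the 10 splits gave as many as the real 25, and the highest other was 29.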
